A study of Mus musculus with 4 samples.

How the data were processed

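RNA sequencing was used to measure gene expression in BV2 cells, an immortalised mouse microglial line, labelled as carrying a CRISPR-Cas9 knockout of PU.1. PU.1 is the ETS family transcription factor encoded by Spi1. The 4 libraries fall into 2 untreated and 2 treated with lipopolysaccharide (LPS), the bacterial ligand of the receptor TLR4, at 10 ng/ml. Wild-type cells are not used here, so no effect of the genotype was measured. The labels give the LPS exposure as 2 h in the source name and as 4 h in the title, and which of them holds was not settled.

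Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into strand-specific paired-end libraries. The extraction text also names human mesenchymal stem cells, while the organism field and the gene symbols are mouse. The submitters' processing notes name CASAVA 1.8.2, Trimmomatic 0.33, STAR 2.5.1, DESeq2 and the human build hg19, and the annotation is not given in the sources used here. Because of that conflict over the build, no coordinates are printed. The deposited values are raw read counts per gene in the layout of STAR's gene count output, with 4 summary lines, 24411 gene symbols and 3 columns that count unstranded, forward-strand and reverse-strand reads. The authors did not normalise or pool these counts. Such counts hold uniquely placed reads, so genes with near-identical copies (the Ifit, Ifi200, Bcl2a1, Gbp and Schlafen families, histones and MHC class I genes) are uncertain.

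The reverse-strand column was used, because its gene total was 78.7 to 95.3 times that of the forward-strand column. The 4 summary lines stayed out of library sizes and tests. Of uniquely placed reads, 53.0% and 51.8% (untreated replicates 1 and 2) and 59.1% and 57.4% (LPS replicates 1 and 2) fell in no annotated feature. Unmapped reads made up 19.0% to 24.2% of all reads and reads placed at several positions 10.1% to 10.6%. Genes were kept by edgeR's expression filter, which left 9992 of 12982 genes with any count. TMM factors were 1.16 and 1.10 in the untreated and 0.888 and 0.880 in the LPS libraries. Values are given as CPM, read counts relative to the TMM-scaled library size, with the mean ± SD of 2 libraries. The comparison used edgeR 4.0.16 (quasi-likelihood test, robust, two-sided, treatment as the only term) in R 4.3.3, with Benjamini-Hochberg adjusted p below 0.05. The standard error (SE) of a log2 fold change is the fold change divided by the square root of the quasi-likelihood F, an approximation. For a gene without untreated counts the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 untreated counts the ratio is given with its 95% exact interval. Floors and intervals cover counting error only.

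The labels do not say that the libraries came from separate cultures, so the spread between these libraries may be technical. The edgeR p-values of genes measure only that spread, estimated with information pooled across genes. Camera p-values at the preset correlation given below rest mainly on the spread across genes. The exact tests and the resampling of genes further below do not measure spread between libraries either. The 2 libraries of each group differed by more than sampling noise. Chi-square per degree of freedom was 1.52 for the untreated and 2.44 for the LPS pair. It covered genes with at least 20 counts, without 5 abundant entries listed below. The libraries of a group were therefore kept as 2 samples.

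There were 30 gene lists with 450 symbols, of which 6 symbols did not match and 1 matched under an older symbol (Acod1 is listed as Irg1). The 22 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01. An estimated correlation and fry were used as alternatives. The estimated correlation rests on 2 residual degrees of freedom, so that setting has little power and does not decide whether a list stands apart. The genes named are a fixed set of 13, the 10 largest rises and the 10 largest falls by fitted log2 fold change among changed genes with a mean CPM of at least 2 and separated groups, and up to 4 changed genes per list by smallest p. Predicted gene models were passed over for the largest changes. In a list without a changed gene the 2 most abundant members are named. Other members named from a list were chosen after their values were seen. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where stated.

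The alternatives were other scalings (RLE, upper quartile, library size only), DESeq2 1.42.0, no filter beyond 1 count, a filter of CPM at least 1 in 2 libraries, unstranded counts, a replicate block and leaving out each library. After the data were seen, offsets corrected for GC content and a fit without 5 abundant entries (Rn45s, Lars2, Mir6236, Rmrp, Rpph1) were added. Of these, Lars2 is a protein-coding gene. GC content was that of the longest GENCODE vM21 transcript with the same symbol, found for 96.6% of tested genes.

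The scripts were tested on simulated data, drawn for the 9992 genes of the LPS comparison with 200 genes changed. There edgeR recovered 59% of the genes changed 1.5-fold and 94% of those changed 2-fold, with 4.38% false calls. DESeq2 recovered 33% and 77%, with 0% false calls. With a simulated GC trend, the uncorrected fit called 1724 genes, 90.5% of them false, and the corrected fit 157 genes, 3.18% of them false. Of 200 random lists, 6 had a camera p below 0.05. Far fewer genes changed in the simulation than in the data, and all its genes shared the same relative spread beyond counting error. Its error and recovery rates therefore do not carry over to the calls below.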

Results

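Gene expression was measured by strand-specific RNA sequencing in BV2 microglial cells labelled PU.1 knockout, untreated or exposed to LPS at 10 ng/ml, with 2 libraries in each group. Gene counts totalled 4502105 and 4115011 in the untreated and 3256197 and 3749159 in the LPS libraries. Log CPM values correlated across genes at 0.991 within the untreated pair, 0.983 within the LPS pair and 0.847 to 0.851 between the groups. The comparison addressed how cells labelled PU.1 knockout respond to LPS.

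Spi1, which encodes PU.1, was counted in every library, with 844 and 743 reads in the untreated and 745 and 958 in the LPS libraries. Its level rose from 163 ± 2.06 CPM to 275 ± 23.1 CPM (SD, n = 2 each), a log2 fold change of 0.75 (SE 0.09, edgeR adjusted p = 8.8e-10). These counts show transcript of the gene and not the edit, since a small insertion or deletion can leave the transcript in place.

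LPS raised cytokine, chemokine and interferon-response genes, and other genes fell. Tnf, a central inflammatory cytokine, rose from 17.7 ± 2.53 to 845 ± 77.5 CPM (SD, n = 2), 47.4-fold. Ccl2, which attracts monocytes, rose from 3.28 ± 0.0468 to 797 ± 93.0 CPM, 241-fold. Irf7, an interferon regulatory factor, rose from 2.56 ± 0.173 to 235 ± 16.5 CPM, 90.7-fold. Mef2c, a transcription factor of the myeloid lineage, fell from 85.6 ± 5.72 to 26.5 ± 0.267 CPM (log2 fold change -1.69, SE 0.14). Across 9992 genes tested, 5186 changed at an edgeR adjusted p below 0.05, of which 2659 were higher and 2527 lower after LPS. At 2-fold or more, 946 genes were higher and 772 lower. Of the changed genes, 51.3% were higher and 48.7% lower, against 22.4% and 77.6% when libraries were scaled by size alone, a scaling that moved the median log2 fold change of all genes to -0.36.

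By fitted log2 fold change the first 10 genes were Il1a, Mx1, Ifi205, Slfn5, Cxcl10, Ifit3b, Ifit1bl1, Nos2, Traf1 and Ifit3. For genes without untreated counts this order rests on edgeR's prior count, and Irg1, Rsad2, Cmpk2 and Il1b, given below, have measured folds above the bounds of those genes. Il1a, an alarmin cytokine, had 0 and 1 untreated counts against 1118 and 1319 after LPS, a ratio of 3845 (95% exact interval 690 to 151944). Cxcl10, an interferon-induced chemokine, had 1 count in each untreated library against 1150 and 1268, a ratio of 1908 (528 to 15761). Ifit3 had 2 and 1 against 1195 and 1455, a ratio of 1394 (476 to 6763). The remaining 7 had no untreated counts. Mx1, an antiviral GTPase, was at least 214-fold higher, Ifi205 at least 204-fold, Slfn5 at least 173-fold, Ifit3b at least 151-fold, Ifit1bl1 at least 141-fold, Nos2, the inducible nitric oxide synthase, at least 138-fold, and Traf1 at least 133-fold.

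The 10 largest falls were of lowly to moderately expressed genes. Lrrc14b fell from 32.8 ± 1.77 to 1.24 ± 1.26 CPM (log2 fold change -4.63, SE 0.33, edgeR adjusted p = 6.4e-17). Asb10 fell from 22.7 ± 3.62 to 1.30 ± 0.122 CPM (log2 fold change -4.11) and Card14, an activator of NF-kB signalling, from 33.7 ± 0.845 to 3.86 ± 2.88 CPM (-3.16). Frat1 (-3.86), Egr3 (-3.63), Ivl (-3.56), Cxxc5 (-3.35), Dgkg (-3.31), Smtn (-3.25) and Zfp395 (-3.19) fell from untreated means of 5.14 to 13.2 CPM.

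Of 17 tested NF-kB feedback and family genes, 17 rose (17 adjusted over the list alone), with a median log2 fold change of 2.79. Nfkbia, which encodes the inhibitor IkB alpha, rose 7.99-fold from 30.4 ± 0.0770 to 243 ± 6.15 CPM. The deubiquitinase gene Tnfaip3 rose 31.6-fold, Tnfaip2 6.93-fold and the adhesion molecule gene Icam1 7.23-fold. The list's camera adjusted p was 1.6e-10, and the adjusted p with an estimated correlation was 0.118. Of 11 tested cytokine genes, 10 rose (10 adjusted over the list alone), with camera adjusted p = 4.5e-09 and adjusted p = 0.140 with an estimated correlation. The cytokine list has 21 members, 9 of them with under 10 counts over the 4 libraries. Il1b rose from 0.714 ± 0.0718 to 787 ± 35.2 CPM (log2 fold change 10.04, SE 0.18), and the receptor antagonist gene Il1rn rose 27.0-fold. Il6, with no untreated counts and 82 and 105 after LPS, was at least 98.4-fold higher. Tnfsf9 did not pass the test (log2 fold change 0.38). All 11 tested chemokine list genes rose (11 adjusted over the list alone), with camera adjusted p = 8.2e-11 and adjusted p = 0.118 with an estimated correlation. The chemokine list has 19 members, and 8 of them had under 10 counts over the 4 libraries. Ccl4 reached 902 ± 97.0 CPM and Ccl3 1355 ± 112 CPM, from 3.63 ± 0.808 and 78.5 ± 0.647 CPM. The chemokine median log2 fold change was 7.91, or 6.61 with genes lacking untreated counts at their bound.

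The interferon response list had the largest number of risers, 36 of 36 tested genes (36 adjusted over the list alone). Its median log2 fold change was 7.04, or 6.21 with genes lacking untreated counts at their bound. Rsad2, which encodes viperin, rose from 1.02 ± 0.186 to 1168 ± 22.6 CPM. Cmpk2 reached 575 ± 10.5 CPM, Ifit1 533 ± 7.83 CPM and Parp14 748 ± 50.7 CPM, from 0.523 ± 0.199, 0.699 ± 0.363 and 5.11 ± 0.346 CPM. Camera gave an adjusted p of 1.1e-27, and the adjusted p was 0.118 with an estimated correlation. All 10 MHC class I presentation genes rose (10 adjusted over the list alone). The peptide transporter gene Tap1 rose 12.8-fold, H2-K1 2.62-fold, the transactivator gene Nlrc5 2.61-fold and the immunoproteasome gene Psmb9 9.02-fold. Camera adjusted p was 2.6e-06 for this list, and adjusted p = 0.276 with an estimated correlation. Of the MHC class II list, Cd74, the invariant chain, was the 1 tested gene and rose 1.82-fold (SE 0.17 on the log2 scale).

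All 17 tested inflammatory effector genes rose (17 adjusted over the list alone), with a median log2 fold change of 3.94, although Cd86 and Pla2g4a turned negative when libraries were scaled by size alone. Irg1, which encodes the itaconate-producing enzyme, rose from 3.09 ± 0.317 to 3925 ± 127 CPM, 1263-fold. Cd40 rose 187-fold, the cyclooxygenase gene Ptgs2 15.3-fold and the acute-phase gene Saa3 12.1-fold. Camera adjusted p was 4.6e-12, and adjusted p = 0.118 with an estimated correlation. All 17 tested inflammasome and cell death genes rose (17 adjusted over the list alone), with camera adjusted p = 7.9e-09 and adjusted p = 0.140 with an estimated correlation. Among them, the caspase-8 regulator gene Cflar rose 12.7-fold, Bcl2a1b 24.4-fold, Mcl1 3.97-fold and the inflammasome sensor gene Nlrp3 6.53-fold.

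Of 14 tested immediate early genes, 10 rose and 2 fell (12 adjusted over the list alone), with camera adjusted p = 0.0042 and adjusted p = 0.212 with an estimated correlation. Atf3 rose 5.71-fold, Ier3 15.7-fold, Klf6 3.39-fold and Junb 2.46-fold. Egr3 and Nr4a1 fell, with log2 fold changes of -3.63 and -2.08. Of 15 tested negative regulators of signalling, 13 rose (13 adjusted over the list alone), with camera adjusted p = 9.0e-06 and adjusted p = 0.140 with an estimated correlation. The cytokine signalling inhibitor gene Socs3 rose 10.1-fold, Zc3h12a, which encodes an RNase, 8.35-fold, Dusp4 4.30-fold and Peli1 3.13-fold.

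**Figure D1:**
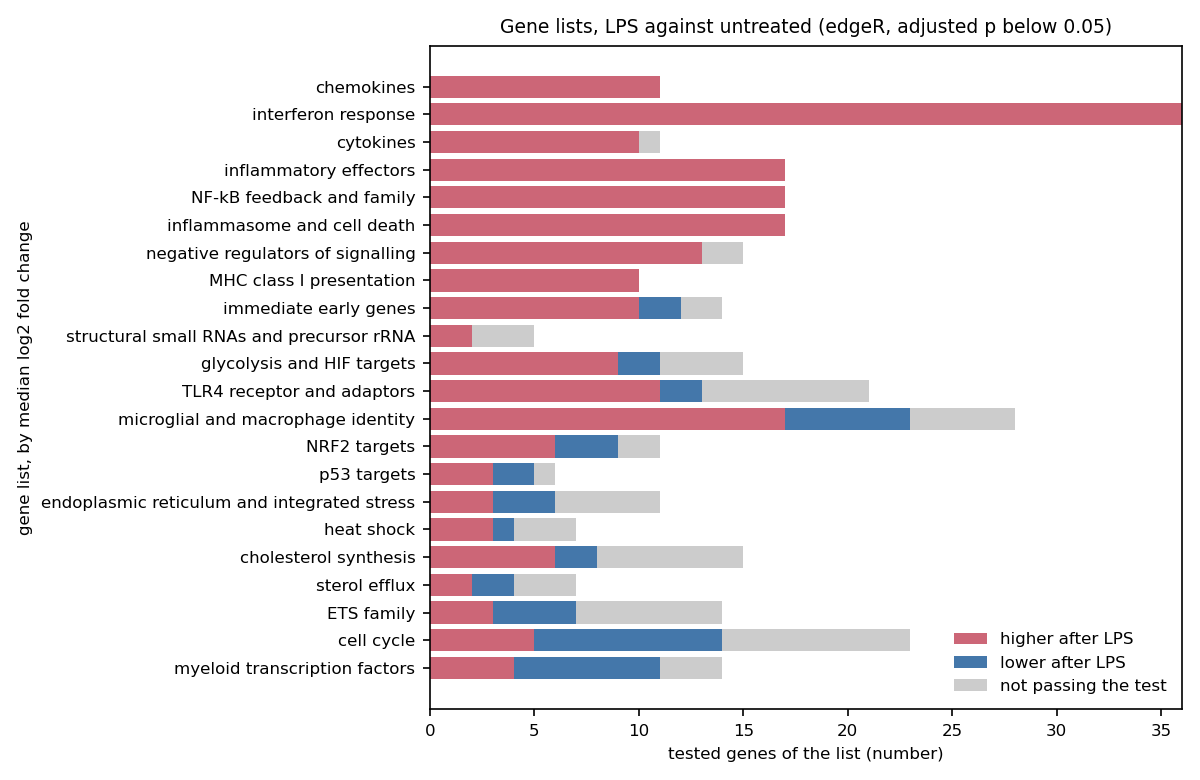
Number of tested genes (horizontal axis) of each gene list with at least 5 tested genes that were higher, lower or not passing the edgeR test after LPS, with lists ordered by median log2 fold change. The interferon response bar holds 36 higher genes, while the cell cycle bar holds 5 higher and 9 lower genes.

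Among 21 tested TLR4 receptor and adaptor genes, 11 rose and 2 fell (14 changed adjusted over the list alone), with camera adjusted p = 0.0056 and adjusted p = 0.212 with an estimated correlation. The LPS co-receptor gene Cd14 rose from 74.5 ± 0.388 to 1191 ± 63.3 CPM, 16.0-fold. Tlr2 rose 9.21-fold, the kinase gene Ikbke 13.8-fold and Irak2 6.99-fold. Tlr4 itself was at 42.3 ± 2.62 CPM untreated and 51.9 ± 1.79 CPM after LPS (log2 fold change 0.29, SE 0.13, edgeR adjusted p = 0.0545), which did not pass the test and turned to -0.0670 with scaling by library size alone. Tab1 and Irak1 fell (log2 fold changes -0.58 and -0.30), but no member of the list was lower after GC correction, while 6 were lower and 9 higher with scaling by library size alone.

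The microglial and macrophage identity list moved both ways, with 17 of 28 tested genes higher and 6 lower (23 adjusted over the list alone). The oxidase subunit gene Cybb rose 9.93-fold, the Fc receptor gene Fcgr1 4.07-fold and Itgam, which encodes CD11b, 4.60-fold. Laptm5 fell from 706 ± 48.0 to 268 ± 21.4 CPM (log2 fold change -1.40), Tmem119, a microglial marker, from 19.1 ± 4.28 to 5.46 ± 0.863 CPM (-1.78) and Mertk, a phagocytic receptor gene, from 18.9 ± 0.522 to 5.94 ± 2.39 CPM (-1.70). Csf1r, the receptor of the survival factor CSF1, was at 389 ± 17.3 and 337 ± 38.4 CPM (log2 fold change -0.21, SE 0.09, edgeR adjusted p = 0.0432). The Csf1r call was lost with DESeq2 (adjusted p = 0.141), and its log2 fold change was 0.00263 after GC correction. The list's camera adjusted p was 0.0269, against 0.0556 without LPS replicate 1, 0.112 without LPS replicate 2 and adjusted p = 0.282 with an estimated correlation. C1qb and Ctss, counted among the risers, turned negative with scaling by library size alone, under which 12 genes of the list were higher and 9 lower.

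Of 14 tested myeloid transcription factors other than PU.1, 7 fell and 4 rose (11 adjusted over the list alone), and the list did not stand apart (camera adjusted p = 0.485). Bhlhe40 fell from 38.2 ± 3.33 to 7.67 ± 1.40 CPM (log2 fold change -2.33) and Cebpa from 95.3 ± 7.60 to 42.7 ± 3.10 CPM (-1.15), while Maf rose 2.69-fold. Of 14 tested ETS family genes, the family of PU.1, 3 rose and 4 fell (7 adjusted over the list alone), with camera adjusted p = 0.692. With scaling by library size alone, 2 rose and 7 fell. Ets2 rose 2.80-fold and Etv3 1.72-fold, and Erf and Elf2 fell (log2 fold changes -1.36 and -0.91).

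**Figure D2:**
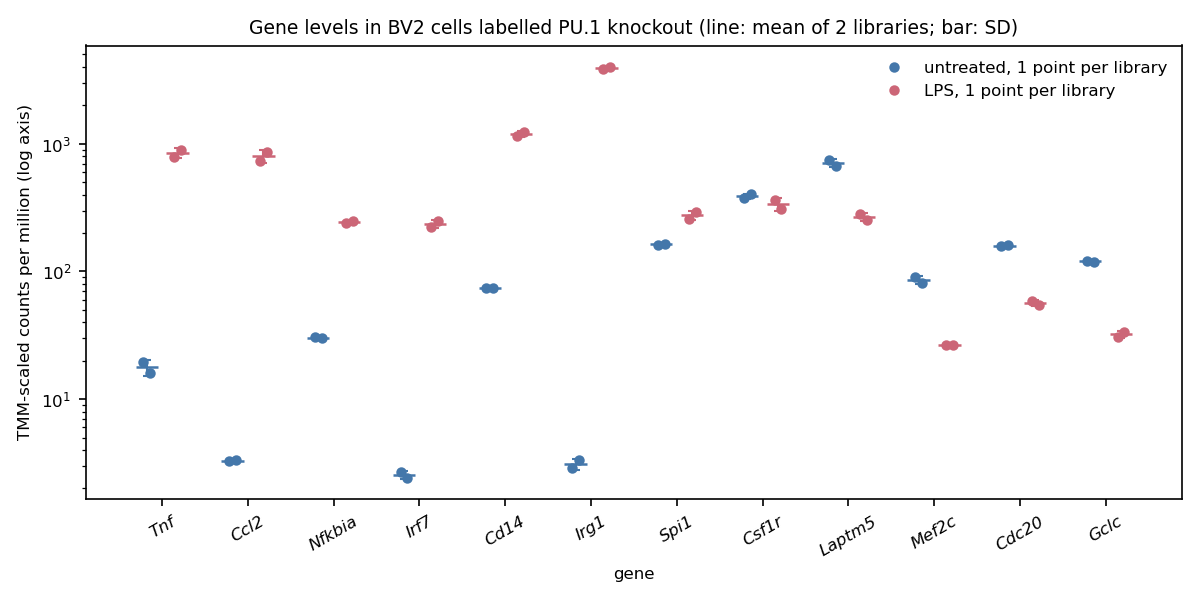
TMM-scaled CPM (vertical log axis) of 12 genes in the untreated and LPS libraries, with 1 point per library, lines at the mean and bars for the SD (n = 2). Cd14 rose from 74.5 to 1191 CPM and Mef2c fell from 85.6 to 26.5 CPM, while the Csf1r libraries lie close to each other.

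Of 15 tested glycolysis and HIF genes, 9 rose and 2 fell (13 adjusted over the list alone), with camera adjusted p = 0.0255, 0.0504 without LPS replicate 2 and adjusted p = 0.258 with an estimated correlation. The glucose transporter gene Slc2a1 rose 5.29-fold and Hif1a 2.42-fold, while the hexokinase gene Hk1 fell (log2 fold change -1.56). Egln3 had 2 and 1 untreated counts against 39 and 34, a ratio of 38.4 (95% exact interval 12.6 to 190). Of 11 NRF2 targets, 6 rose and 3 fell (10 adjusted over the list alone), with camera adjusted p = 0.521. Slc7a11, a cystine transporter gene, rose 7.77-fold, Srxn1 2.58-fold and Prdx1 2.13-fold, whereas Gclc, an enzyme gene of glutathione synthesis, fell from 120 to 32.1 CPM (log2 fold change -1.90, SE 0.12). Of 15 cholesterol synthesis genes, 6 rose and 2 fell (8 adjusted over the list alone, camera adjusted p = 0.531). Insig1 rose 1.61-fold and Msmo1 1.56-fold, and Dhcr7 fell (-0.74 on the log2 scale), as did Srebf2 (-0.52), whose call was lost after GC correction. Of 7 sterol efflux genes, 2 rose and 2 fell (4 adjusted over the list alone, camera adjusted p = 0.930), with the transporter gene Abca1 3.24-fold higher and Srebf1 lower (log2 fold change -0.86). Nr1h3 rose 1.65-fold and Mylip fell (log2 fold change -0.55), and neither passed with DESeq2 (adjusted p = 0.0535 and 0.0603). Nr1h3 did not pass with scaling by library size alone either (adjusted p = 0.0792).

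Of 23 cell cycle genes, 9 fell and 5 rose (14 adjusted over the list alone), with camera adjusted p = 0.296. The mitotic genes Cdc20, Plk1, Ccnb2 and Aurkb fell, with log2 fold changes of -1.50, -1.28, -1.29 and -1.32. Among the risers were the DNA replication gene Mcm6 (log2 fold change 0.66) and E2f1 (0.60). Of 11 endoplasmic reticulum and integrated stress genes, 3 rose and 3 fell (7 adjusted over the list alone, camera adjusted p = 0.760). The chaperone gene Hspa5 rose 2.71-fold, and Ddit4, Xbp1 and Asns fell (log2 fold changes -2.13, -0.49 and -0.45). Of 7 heat shock genes, 3 rose and 1 fell (4 adjusted over the list alone, camera adjusted p = 0.505). Hspd1 rose 1.54-fold. Hspe1 rose 1.38-fold but did not pass with scaling by library size alone (adjusted p = 0.391), Hsp90aa1 rose 1.27-fold but turned to -0.0108 on the log2 scale with scaling by library size alone, and Bag3 fell (-1.26), without passing under DESeq2 (adjusted p = 0.0528). Of 6 p53 targets, 3 rose and 2 fell (5 adjusted over the list alone, camera adjusted p = 0.587). The cell cycle inhibitor gene Cdkn1a rose 12.2-fold, Mdm2 4.36-fold and Ccng1 1.63-fold, while Sesn1 fell (log2 fold change -2.08). With scaling by library size alone the median log2 fold change turned negative for NRF2 targets (-0.0116), cholesterol synthesis (-0.29), sterol efflux (-0.28), endoplasmic reticulum and integrated stress (-0.14), heat shock (-0.17) and p53 targets (-0.09). Cell cycle genes then split into 1 higher and 14 lower.

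Markers of other cell types were at or near 0, apart from the endothelial markers Kdr and Vwf, which could be tested. No fibroblast, astrocyte, neuron, lymphocyte or epithelial marker had enough counts to be tested. The most abundant fibroblast, astrocyte and lymphocyte markers had means over the 4 libraries of 0.249 CPM (Pdgfrb, fibroblasts), 0.0759 CPM (Gfap and S100b, astrocytes) and 0.124 CPM (Cd79b, lymphocytes). Neuron and epithelial markers, such as Rbfox3, Snap25, Epcam and Krt8, had 0 counts, as did Col1a1, Mbp and Cd3e. Of the endothelial markers, Kdr rose from 14.5 ± 0.539 to 28.4 ± 2.43 CPM (log2 fold change 0.96), Vwf did not pass, and the other 4 could not be tested. Of the structural RNA list (Rn45s, Rmrp, Rpph1, Rnu11 and Rnu12), Rn45s and Rpph1 rose 1.55-fold and 1.44-fold (4 changed adjusted over the list alone, camera adjusted p = 0.193, or 0.0225 after GC correction and 0.0305 without LPS replicate 1). Rpph1 did not pass with scaling by library size alone (adjusted p = 0.109). Rn45s, the ribosomal RNA precursor, took 14.6% to 20.9% of the gene counts of a library. Its level was 149071 ± 33554 CPM untreated and 231729 ± 6378 CPM after LPS (SD, n = 2). The untreated replicates 1 and 2 lay far apart, at 125345 and 172797 CPM. How far ribosomal RNA was depleted in each library was not measured, and its part in the Rn45s rise was not tested.

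With DESeq2, 3176 genes changed, and across genes the log2 fold change fell with GC content, from a median of 0.31 in genes of 29.6% to 41.2% GC to -0.37 in genes of 57.5% to 72.5% GC. All 12 lists that passed with camera lost their call when the correlation between genes was estimated, a setting with little power at 2 residual degrees of freedom.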

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

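The tests of a leak between strands were chosen after the result was seen, and the test of neighbouring genes before it. The column that counts reads on the strand opposite to each gene, which no comparison above uses, held 1.04% to 1.26% of the stranded gene counts of a library. Of 718 genes that could be tested in it with edgeR, 156 were higher after LPS and 85 lower, and 188 were higher at an unadjusted p below 0.05. The smallest adjusted p-values among the risen were those of Tmem132a (39 and 32 counts untreated, 456 and 493 after LPS, log2 fold change 4.40), Gm14023 (0 and 1 against 412 and 412, fitted log2 fold change 9.96, ratio 1300 with a 95% exact interval of 233 to 51416) and Gm15441 (190 and 165 against 410 and 484, log2 fold change 1.99).

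Of the 156 genes, 72 had opposite-strand counts of at least 10% of their own strand in the LPS libraries. In 50 of the 72 the opposite strand held more counts than the own strand, for 49 beyond counting error (exact binomial test, one-sided), which argues against a leak of their own strand for these 49. For the other 23, with shares of 12.1% to 133%, all 23 counts exceeded a leak at 0.842%, the 90th percentile of 2822 abundant genes (exact binomial test, Bonferroni over 718 genes, largest p = 3.8e-20). These 23 were chosen for a share of at least 10%, so that outcome was nearly fixed beforehand. It does not decide whether a leak of their own strand is behind their counts. Among those of the 72 with a gene model in GENCODE vM21, 75% (51 of 68) had a risen gene on the other strand overlapping or within 10 kb, against 23.2% (97 of 419) of other such genes (Fisher's exact test, two-sided, p = 2.2e-16). Reads of an oppositely oriented neighbour that rose are thus a candidate explanation, with Slc15a3 beside Tmem132a, Il1a beside Gm14023 and Txnip beside Gm15441, while antisense transcripts of the genes themselves stay open and no biological explanation was tested.

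The other 84 genes had opposite-strand counts under 10% of their own strand. Over 145 of the 200 most abundant genes, those not called higher on the opposite strand, the opposite-strand share was 0.108% and 0.106% in the untreated and 0.164% and 0.402% in the LPS libraries. The lower LPS share exceeded the higher untreated share by 0.60 on the log2 scale (95% interval 0.28 to 0.91, from 2000 resamplings of the genes). The interval covers the spread over genes and not that between libraries. For these genes and libraries, the values argue against a leak at one rate as the only source of the reads. A leak at one rate together with other opposite-strand reads that rose stays open. A higher leak rate in the LPS libraries stays open, with a log2 change between the groups of 1.41, or 0.62 without LPS replicate 2. The LPS pair differed by 1.30, and the leak rate cannot be told apart from other opposite-strand reads that rose in these libraries, because each library belongs to 1 group.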

How the results depend on the processing

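The GC-corrected fit and the fit without the 5 abundant entries were chosen after the data were seen. Against 5186 changed genes, the edgeR alternatives called 4063 (without untreated replicate 2) to 6157 (library size only). With library size only, 1379 genes were higher and 4778 lower, 1602 of them at least 2-fold lower, which follows from leaving out the composition factors (median log2 shift -0.36). Upper quartile scaling moved that median to -0.10. DESeq2 called 3176 genes, 1766 higher and 1410 lower, of which 3134 were shared with edgeR and all of these had the same direction. The cause of the lower number was not tested. GC correction called 4936 genes, 4184 of them shared, and 1677 of the 1718 genes changed at least 2-fold stayed called at any fold. At least 2-fold it called 967 higher and 604 lower genes, against 946 and 772. Leaving out each library gave 4063 to 4917 changed genes, with the lone library of a group assumed to vary like the other group.

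Of the gene lists, 12 passed in the main test, 18 with fry and 0 with an estimated correlation. The last setting rests on 2 residual degrees of freedom and has too little power to decide whether the lists stand apart. The endoplasmic reticulum and integrated stress list, which did not pass, turned direction without LPS replicate 2 (adjusted p = 0.803; range 0.324 to 0.888 without each library), and the cause was not tested.

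Among 111 named genes tested, reversals were of Tlr4 (-0.0670) and Hsp90aa1 (-0.0108) with library size only and of Tlr4 (-0.00412) and Csf1r (0.00263) after GC correction. The first follow from the shift of all genes, and the GC ones from a trend whose cause was not tested. Csf1r also lost its call without untreated replicate 1, untreated replicate 2 or LPS replicate 2 (log2 fold changes -0.26, -0.17 and -0.09), and Hsp90aa1 lost its call without untreated replicate 2 (0.29). No named gene changed its call with RLE or upper quartile factors, either filter or unstranded counts.

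Both groups use the replicate numbers 1 and 2, and the labels do not say whether equal numbers pair an untreated and an LPS culture. The deviations of equally numbered libraries correlated at -0.04 across genes. A replicate block gave 5171 changed genes and 12 lists and changed no call of a named gene or list. Depth limits the lowest genes, for which 3 counts over a group equal 0.308 CPM untreated and 0.485 CPM after LPS.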

Other observations

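The lists and families in this part and the tests of GC content and Spi1 were chosen after the data were seen. Camera p-values of the lists were adjusted over these later lists alone. After that choice they describe the lists and are no independent evidence. All 12 tested interferon-inducible GTPase genes, which restrict pathogens inside cells, rose (camera adjusted p = 3.5e-12, and adjusted p = 0.0777 with an estimated correlation). Gbp2, Gbp3, Gbp5, Igtp, Irgm1, Ifi47, Mx1 and Mx2 were also on the interferon response list, so this is not independent of that result. Irgm1 rose from 20.8 ± 2.43 to 524 ± 43.0 CPM (SD, n = 2). All 6 tested Schlafen genes rose (camera adjusted p = 2.0e-06, and adjusted p = 0.0777 with an estimated correlation), with Slfn2 going from 5.65 ± 1.74 to 464 ± 14.5 CPM. Of 12 nucleotide sensor genes, 11 rose and Tmem173, which encodes STING, fell (log2 fold change -0.29, edgeR adjusted p = 0.0431), though Tmem173 did not pass after GC correction (adjusted p = 0.177). Among the sensors, Zbp1, Ifi204, Ifi205, Ddx58, Ifih1 and Dhx58 were on the interferon response list too. Of 11 cathepsin genes, 9 rose and 2 fell (camera adjusted p = 0.0098, and adjusted p = 0.404 with an estimated correlation), or 5 and 2 with library size only, and Ctsk rose from 865 ± 30.4 to 4695 ± 271 CPM. Of 12 circadian clock genes, 7 fell and 1 rose (camera adjusted p = 0.0030, and adjusted p = 0.124 with an estimated correlation). Tef fell from 35.4 ± 1.88 to 11.5 ± 0.531 CPM, and the transcription factor gene Clock rose from 7.05 ± 0.582 to 14.1 ± 3.60 CPM. Of 7 Notch pathway genes, 3 fell and 1 rose, and the list did not stand apart (camera adjusted p = 0.348). Hes1 and Hey1 fell from low levels of 3.77 and 4.75 CPM (log2 fold changes -2.85 and -2.83), and Notch1 rose (1.87). Dtx3 also fell (-0.63), but did not pass after GC correction (edgeR adjusted p = 0.327).

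Gene families were also formed from shared symbol stems, and 6 of 152 passed with camera, none with an estimated correlation (adjusted p = 0.983). They were Ccl, Ifi, the C-type lectins (6 of 9 rose), the TNF receptor family (9 of 11 rose, 4 with library size only), the annexins (7 of 9 rose) and the histones. Clec4e, a receptor for fungal and mycobacterial glycolipids, rose from 9.83 ± 2.33 to 617 ± 28.2 CPM, and Anxa1 from 60.2 ± 8.18 to 276 ± 15.6 CPM. Of 53 histone genes, 34 fell and 2 rose, with a median log2 fold change of -0.38 (quartiles -0.63 and -0.17). After GC correction 20 fell and 9 rose, the median was -0.17 (quartiles -0.37 and 0.19) and the family no longer passed (adjusted p = 0.841), their median GC content being 57.8%. The 261 genes of the Zfp family passed only after GC correction (adjusted p = 0.0068, with 53 lower and 24 higher, against 0.809, 45 and 41 without it). With library size only, 108 of them were lower and 11 higher. Ifnb1, the interferon beta gene, had 0 counts in both untreated libraries and 3 and 2 after LPS. Il27 had 0 and 0 against 6 and 5, and Il10, Il12a and Csf2 had 0 in every library. Lars2 took 2.39% and 2.43% of gene counts untreated and 5.79% and 5.33% after LPS. The nuclear RNA Malat1 rose from 584 ± 16.0 to 2860 ± 530 CPM.

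Genes of low GC content were higher and genes of high GC content lower after LPS, with a slope of -0.35 on the log2 scale per 10% GC over 8155 genes. Of the genes changed at 2-fold or more, 97.6% stayed called in the same direction, at any fold, after correction. A trend with medians from 0.31 to -0.37 across GC groups could seldom turn the direction of genes chosen at 2-fold or more. That share was thus largely fixed beforehand and does not decide on a GC bias behind these changes. The number past 2-fold moved, to 967 higher and 604 lower genes, against 946 and 772 before correction. For the trend itself, the slope differed within the untreated pair by 24.2% and within the LPS pair by 6.09% of the difference between the groups. A library bias and an effect of LPS on the trend cannot be told apart, because each library belongs to 1 group. Fold sizes and smaller changes are left open, as for Csf1r (-0.21 before and 0.00263 after correction).

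Spi1 was counted in all 4 libraries of cells labelled as knockout. The lowest count of 743 argues against a deletion that removes the whole transcript from every copy of the gene in all cells. An edit that leaves the transcript in place, or cells with an unedited gene, could give counts up to the 958 seen, and these cannot be told apart because gene counts do not hold the edited bases. The rise of Spi1 after LPS remained after GC correction (log2 fold change 1.11, edgeR adjusted p = 2.7e-15). Wild-type levels are not analysed here.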
